A study of Homo sapiens with 24 samples.

How the data were processed

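The data are sgRNA read abundances from 2 pooled lentiviral screens with 4 barcoded Cas9 effectors each. Per the labels' protocols, each effector with its guide library was transduced separately, the cultures were kept apart and were combined only for antibody staining and sorting, so each effector is 1 culture per screen. Genomic DNA was amplified in 2 rounds of PCR without molecular identifiers named in the labels, and PCR reads are not independent molecules, so read-based intervals cover counting error only. Bowtie and build hg38 are named in the submitters' processing notes; the version of Bowtie, filters and any constant added to counts are not given in the sources used here.

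The deposited tables hold log2 values per guide and library, 1 table per screen. The linear values of the 4 effectors of a sort state sum to 1000000 together, so each deposited log2 value is scaled to the whole pool rather than to 1 library. All linear values were whole multiples of 1 step per sort state, within 2.0e-10 of a read in the nuclease table and 7.5e-11 in the activation table, and reads were recovered by dividing by that step. A constant added to each count before scaling cannot be excluded, and no guide has fewer than 8 reads in any library. Library groups were read from the sample titles; all value columns were mapped. The design text and the sample labels write the melanoma line differently, and the labels' A375 is used.

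From the linear values, log2((sorted + 1)/(presort + 1)) was computed per guide and effector with a pseudocount of 1 on that scale, for guides with at least 20 recovered presort reads (0 to 11 guides per effector were left out), and the median of the 250 non-targeting guides of the same library pair was subtracted. Because each group has 1 library, no count model was fitted and no p-value is given. Median folds carry exact 95% order-statistic intervals over guides, shares carry Clopper-Pearson intervals, and named guides carry exact binomial intervals of the read ratio with the centre held fixed. Random lists (10000 per class) were drawn from the other guides of a library within 10 strata of presort abundance. Guides past the 95th percentile of the non-targeting guides were counted as enriched. The region of effect is the coding segments for the nuclease and the promoter window within 500 nt of the RefSeq start of PTPRC for activation. Guide coordinates are those of the files, in hg38, and the gene bounds those of a RefSeq table for GRCh38; the table holds no exons, so introns, untranslated regions and the first coding segment were not annotated here. Spacer sequences were not used here.

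Guides were named by a rule fixed before the data were examined: per screen and effector, among guides enriched in the expected bin and below the centre in the opposite bin, the 3 with the highest log2 fold and the highest of each of NGG, NGH and NHN. Alternatives fixed at the same time were other centring, pseudocounts of 0.1 and 10, presort minimums of 0 and 100 reads, guides past the minimum with all effectors, the 99th percentile, a fixed 2-fold threshold, enrichment with a fold below 0 in the opposite bin, the expected over the opposite bin, rank correlation, PAM classes alone and 50-nt bins. A background by presort abundance was added after seeing the data: a lowess curve (fraction 0.5) of fold on log2 presort abundance over non-targeting guides and guides outside the region of effect (promoter NHN guides for the nuclease, coding guides for activation), subtracted from each guide.

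The median guide had 263 to 691 presort reads across effectors. The standard deviation of non-targeting folds was 0.15 to 0.19 in the nuclease screen and 0.20 to 0.30 in the activation screen, against 0.081 to 0.10 and 0.066 to 0.12 from read counting alone. The computation was tested on simulated data with 200 of 2109 guides changed: a simulated log2 fold of 0.5 was recovered as a median of 0.49 to 0.53 in nuclease libraries and 0.48 to 0.53 in activation libraries, and a fold of 1 as 0.98 to 1.00 and 0.97 to 1.01. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.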

Results

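Guide abundance was measured by sequencing sgRNA cassettes from the genomic DNA of 2 pooled screens against CD45. CD45 is the receptor-type tyrosine phosphatase encoded by PTPRC and displayed on the surface of white blood cells. In the nuclease screen, K562 cells, a human chronic myeloid leukaemia line that displays CD45, carried a cutting Cas9, and guides that disrupt PTPRC were sought in the 10% of cells with the least CD45. In the activation screen, A375 cells, a human melanoma line, carried a cleavage-dead Cas9 fused to the VPR transcriptional activator, and guides that switch PTPRC on were sought in the 10% with the most CD45. Each screen used 4 effectors: SpCas9, which prefers an NGG PAM beside the target, and 3 variants with a relaxed PAM preference, xCas9, Cas9-NG and xCas9-NG. Each effector was sequenced before sorting, in the top 10% and in the bottom 10%, which gives 24 groups of 1 library each. No library has a replicate, so differences between effectors are differences between these libraries, and intervals cover the spread over guides or counting error only.

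The library held 2109 guides, of which 250 were non-targeting. The 1859 targeting guides lay on chromosome 1 (hg38) in 2 blocks. A promoter window ran from 198637510 to 198640504 and held 1125 guides, and coding segments between 198692347 and 198728444 held 734. PTPRC itself spans 198638713 to 198757476 on the plus strand in RefSeq. By PAM, 176 targeting guides were NGG, 783 were NGH (NGA, NGC or NGT) and 900 were NHN (NAN, NCN or NTN). Recovered reads per library ran from 600407 to 1687655 in the nuclease screen and from 565270 to 1833689 in the activation screen. Folds below are log2 of sorted over presort abundance, with the median of the non-targeting guides set to 0.

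The first comparison asked which PAMs each nuclease could use to remove CD45. Guides against the coding sequence with an NGG PAM were concentrated in the CD45-low cells with every effector, most with SpCas9. Their median log2 fold in the bottom bin was 1.13 (95% interval 0.85 to 1.23) with SpCas9, 0.60 (95% interval 0.46 to 0.69) with xCas9, 0.67 (95% interval 0.56 to 0.84) with Cas9-NG and 0.57 (95% interval 0.47 to 0.74) with xCas9-NG. Coding NGH guides stood at 0.24, 0.26, 0.31 and 0.27 with SpCas9, xCas9, Cas9-NG and xCas9-NG, the highest with Cas9-NG, and coding NHN guides at 0.10, 0.12, 0.14 and 0.13. In the CD45-high cells the same NGG guides lay below the non-targeting guides, at -0.54, -0.13, -0.28 and -0.17 in that order. Coding NGH guides stood there at -0.032 (-0.067 to 0.0076), 0.040 (0.018 to 0.065), -0.093 (-0.13 to -0.048) and -0.031 (-0.069 to -0.0068). With xCas9 they thus lay above the non-targeting guides in both bins, and the SpCas9 interval includes 0.

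**Figure D1:**
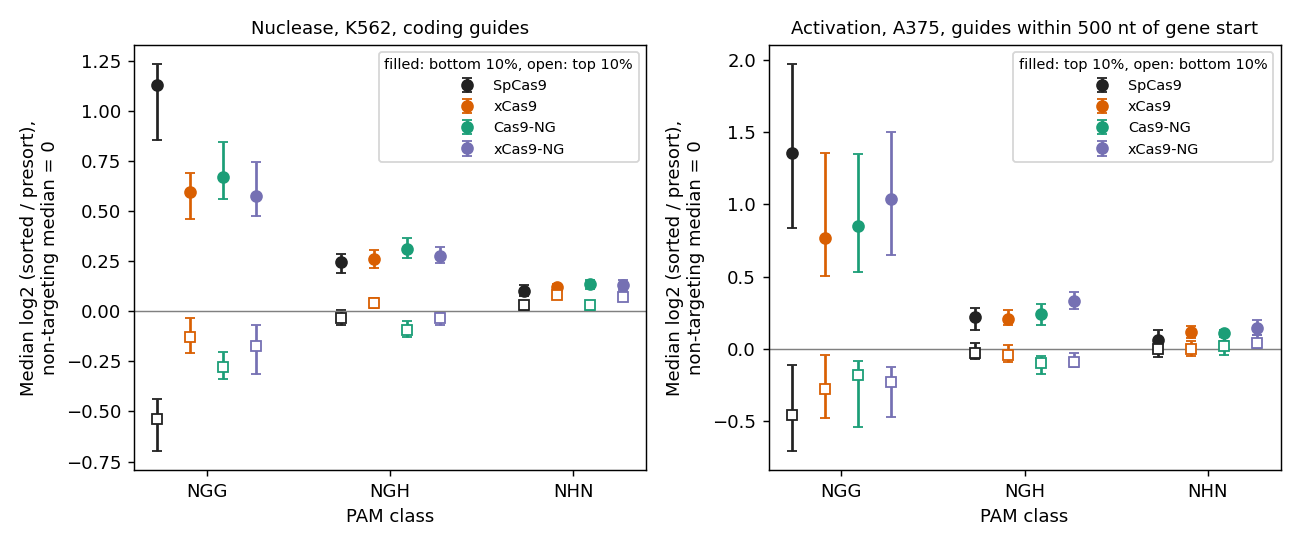
Median log2 fold of guides by PAM class and effector (points) with exact 95% order-statistic intervals over guides (bars), for the bin where the effect was sought (filled) and the opposite bin (open). Coding NGG guides of the SpCas9 nuclease sit at 1.13 in the bottom bin and -0.54 in the top bin, and NGG guides within 500 nt of the gene start sit at 1.35 in the top bin of SpCas9 activation.

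Counted guide by guide, 48 of 52 (92.3%, 81.5 to 97.9%) coding NGG guides of SpCas9 passed the 95th percentile of the non-targeting guides (share with its exact Clopper-Pearson interval), with 43 of 53 (81.1%, 68.0 to 90.6%) for xCas9, 44 of 53 (83.0%, 70.2 to 91.9%) for Cas9-NG and 45 of 53 (84.9%, 72.4 to 93.3%) for xCas9-NG. Among coding NGH guides, 101 of 230, 85 of 231, 121 of 231 and 110 of 231 passed with SpCas9, xCas9, Cas9-NG and xCas9-NG, and among coding NHN guides 102 of 447, 80 of 448, 103 of 447 and 115 of 449. The 95th percentile itself was 0.28, 0.34, 0.29 and 0.29 in that order, so counts also follow the non-targeting spread of each library. At the 99th percentile the NGH counts were 46, 55, 93 and 76, which turns the order of SpCas9 and xCas9, and at a fixed 2-fold 0, 3, 21 and 11. Guides that also lay below 0 in the CD45-high bin numbered 45, 34, 36 and 36 for NGG, 57, 35, 85 and 64 for NGH, 20, 9, 26 and 18 for NHN and 2, 1, 1 and 1 for the non-targeting guides. The medians of coding NGG and coding NGH guides were higher than those of all 10000 random guide lists matched on presort abundance, with every effector. Folds of the non-targeting guides fell with presort abundance, with slopes of -0.093 to -0.081 log2 per doubling in the bottom bin, and NHN guides were less abundant before sorting than non-targeting guides. Against an abundance-dependent background, a setting chosen after seeing the data, coding NGH medians were 0.11, 0.12, 0.19 and 0.13 and coding NHN medians 0.0031, 0.0095, 0.018 and 0.012; that background was fitted partly on promoter NHN guides, so NHN values near 0 are in part set by it.

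Set against SpCas9 guide by guide, the 3 variants were lower at NGG, and Cas9-NG and xCas9-NG were somewhat higher at NGH, while the interval of xCas9 at NGH includes 0. Over all guides the NGH difference turned to -0.58 for xCas9 and -0.10 for xCas9-NG without centring, and to -0.025 for xCas9 with the bottom over the top bin. Over coding NGG guides the median paired difference in log2 fold was -0.52 (-0.57 to -0.33, higher in 3 of 52 guides) for xCas9, -0.31 (-0.40 to -0.25) for Cas9-NG and -0.42 (-0.50 to -0.30) for xCas9-NG. Over coding NGH guides it was 0.023 (-0.0068 to 0.052) for xCas9, 0.12 (0.087 to 0.15) for Cas9-NG and 0.063 (0.040 to 0.10) for xCas9-NG. The difference was not even across NGH: for Cas9-NG it was 0.21 (0.15 to 0.30, higher in 72 of 87 guides) at NGT, 0.087 (0.029 to 0.15) at NGC and 0.051 (0.021 to 0.12) at NGA. For xCas9-NG it was 0.13 (0.071 to 0.19) at NGT, 0.11 (0.034 to 0.17) at NGC and -0.0092 (-0.046 to 0.042) at NGA. The non-targeting guides, measured the same way, differed by -0.0019 (-0.023 to 0.015) for Cas9-NG and 0.0080 (-0.019 to 0.037) for xCas9-NG. Coding NHN guides differed by 0.032 (0.011 to 0.051) for Cas9-NG and 0.024 (-0.0091 to 0.044) for xCas9-NG. Within these, NAN guides differed by 0.056 (0.018 to 0.10) and 0.067 (0.0093 to 0.099), and the NCN and NTN intervals include 0. For both variants the NGA difference is therefore no larger than the NAN difference.

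Among the single PAMs, coding NGT guides ranked next to NGG for all 4 nucleases, with medians of 0.32, 0.35, 0.41 and 0.37 for SpCas9, xCas9, Cas9-NG and xCas9-NG, against 0.26, 0.24, 0.31 and 0.24 for NGA and 0.12, 0.17, 0.23 and 0.23 for NGC. NGC guides were lower than NGT guides by median with each effector, and stood at percentiles 26.8, 77.1, 97.2 and 97.7 of the matched random lists. Outside NG PAMs, NAN guides had the highest medians with Cas9-NG at 0.17 (95% interval 0.14 to 0.21) and with xCas9-NG at 0.19 (95% interval 0.13 to 0.25). These medians stood at percentiles 43.7 and 61.4 of the matched random lists. The lists also drew on NGG and NGH guides, so a middle percentile does not place NAN guides with inactive guides. Of the NAN guides of xCas9-NG, 55 of 150 (36.7%, 29.0 to 44.9%) passed the threshold, against 28.7% of its promoter NHN guides, and they also lay above 0 in the CD45-high bin, at 0.10 (0.041 to 0.14).

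**Figure D2:**
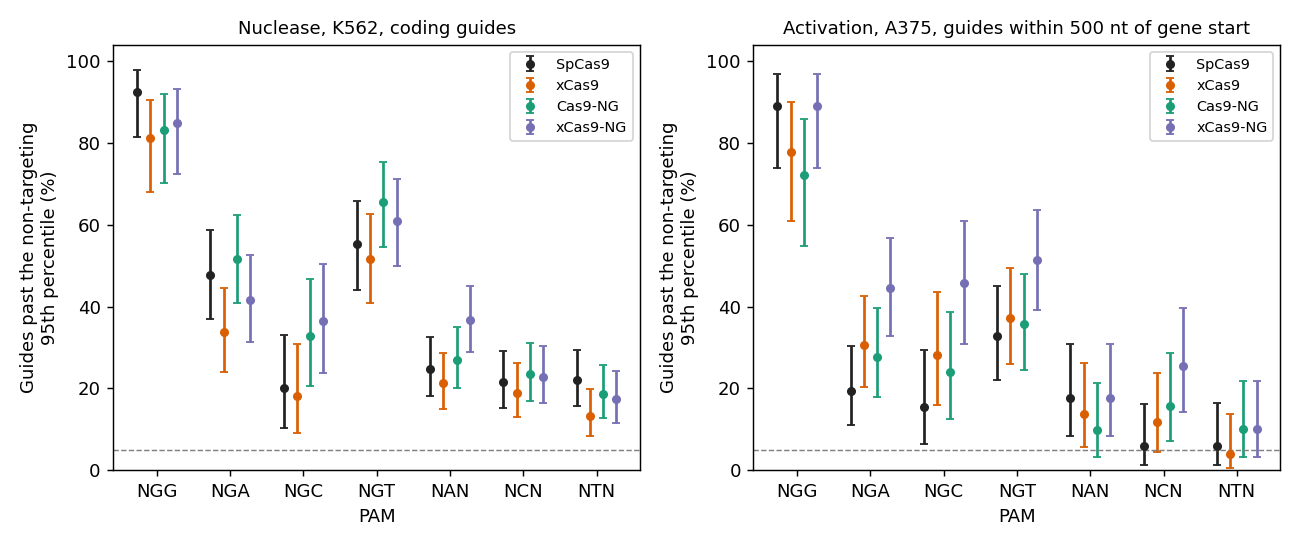
Percent of guides past the 95th percentile of the non-targeting guides (vertical axis) by PAM (horizontal axis) and effector, with exact Clopper-Pearson 95% intervals; the dashed line is the 5% set by the non-targeting guides. At NGT, 65.5% of coding guides passed with the Cas9-NG nuclease and 51.4% of guides within 500 nt of the gene start with xCas9-NG activation. Each library has its own 95th percentile.

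Single nuclease guides reached several-fold enrichment. CCguide_00096 (TGG PAM, minus strand, chromosome 1, 198639276 to 198639295), in the promoter window 572.5 nt past the RefSeq gene start, led with the 3 variants: its log2 fold was 2.33 (2.14 to 2.55; 1432 sorted against 229 presort reads) with xCas9, 2.02 with Cas9-NG and 2.13 with xCas9-NG. It ranked 2 with SpCas9 at 1.93, and its log2 fold in the CD45-high bin was -2.21, -2.45, -2.43 and -2.66 in the order SpCas9, xCas9, Cas9-NG and xCas9-NG. CCguide_04621 (TGG, plus strand, chromosome 1, 198718159 to 198718178, coding segment 13) led with SpCas9 at 1.95 (1.76 to 2.16; 1747 sorted against 240 presort reads) and ranked among the first 3 with every effector. CCguide_00118 (TGG, chromosome 1, 198639277 to 198639296) ranked 3 with SpCas9 at 1.90, CCguide_04631 (AGG, chromosome 1, 198703316 to 198703335, coding segment 6) ranked 3 with xCas9 at 1.69. CCguide_04658 (TGG, chromosome 1, 198718206 to 198718225, coding segment 13) reached 1.65 with Cas9-NG and 1.58 with xCas9-NG.

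The highest NGH guide differed by effector. With Cas9-NG it was CCguide_04694 (TGT, chromosome 1, 198712999 to 198713018, coding segment 11) at 1.59 (1.37 to 1.84; 1082 sorted against 181 presort reads), and this guide stood at 0.72 with SpCas9. With xCas9-NG it was CCguide_00286 (TGT, chromosome 1, 198639326 to 198639345, promoter window) at 1.42, with xCas9 CCguide_00317 (GGT, chromosome 1, 198639275 to 198639294, promoter window) at 1.22, and with SpCas9 CCguide_04717 (AGT, chromosome 1, 198716814 to 198716833, coding segment 12) at 0.94. CCguide_00317 overlaps CCguide_00096 on the same strand. Its PAM starts with GG, so an NGG PAM lies 1 base closer to its spacer. All 4 of the highest NHN guides lay in coding segment 13: CCguide_05226 (ATG) at 1.06 with SpCas9 on 78 presort reads, CCguide_05061 (ACA) at 0.83 with xCas9, CCguide_05036 (CAT) at 1.09 with Cas9-NG and CCguide_04997 (GAT) at 0.79 with xCas9-NG. CCguide_05226 was not enriched with the other 3 effectors, at 0.15, -0.059 and 0.17. It spans 198718158 to 198718177 on the plus strand and so starts 1 base before CCguide_04621. The TGG PAM of CCguide_04621 therefore lies 1 base further from its spacer, and whether SpCas9 used that PAM was not tested.

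By position, each coding segment with NGG guides carried enrichment with SpCas9: segment medians of NGG guides ran from 0.80 to 1.46, over 1 to 15 guides each. Segment 13, with the most NGG guides (15), stood at 1.19 (0.99 to 1.52) with SpCas9, 0.64 (0.36 to 0.95) with xCas9, 0.81 (0.59 to 1.19) with Cas9-NG and 0.62 (0.43 to 0.95) with xCas9-NG. NGG guides of the promoter window were far weaker than coding NGG guides, with medians of 0.25, 0.27, 0.27 and 0.28. Promoter NGH medians, at 0.17, 0.18, 0.21 and 0.20, lay less far below those of coding NGH guides. Promoter NHN medians, at 0.13, 0.14, 0.14 and 0.14, were not below those of coding NHN guides. For NGG guides a stretch 500 to 700 nt past the gene start, noticed after the values were seen, stood higher: the 12 NGG guides there had a median of 1.01 (0.20 to 1.56) with SpCas9 and 0.23 was the median of the other 111 promoter NGG guides. With NGG and NGH guides together it did not stand apart: medians were 0.18, 0.18, 0.26 and 0.23 from 500 to 600 nt (38 guides) and 0.49, 0.37, 0.46 and 0.43 from 600 to 700 nt (19 guides), against 0.45, 0.49, 0.47 and 0.52 from 1100 to 1200 nt, where the 7 guides also lay above 0 in the CD45-high bin, at 0.32, 0.13, 0.12 and 0.15. Taken over all regions, NGG medians were 0.36, 0.34, 0.35 and 0.37, NGH medians 0.18, 0.20, 0.23 and 0.22 and NHN medians 0.12, 0.13, 0.14 and 0.14.

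**Figure D3:**
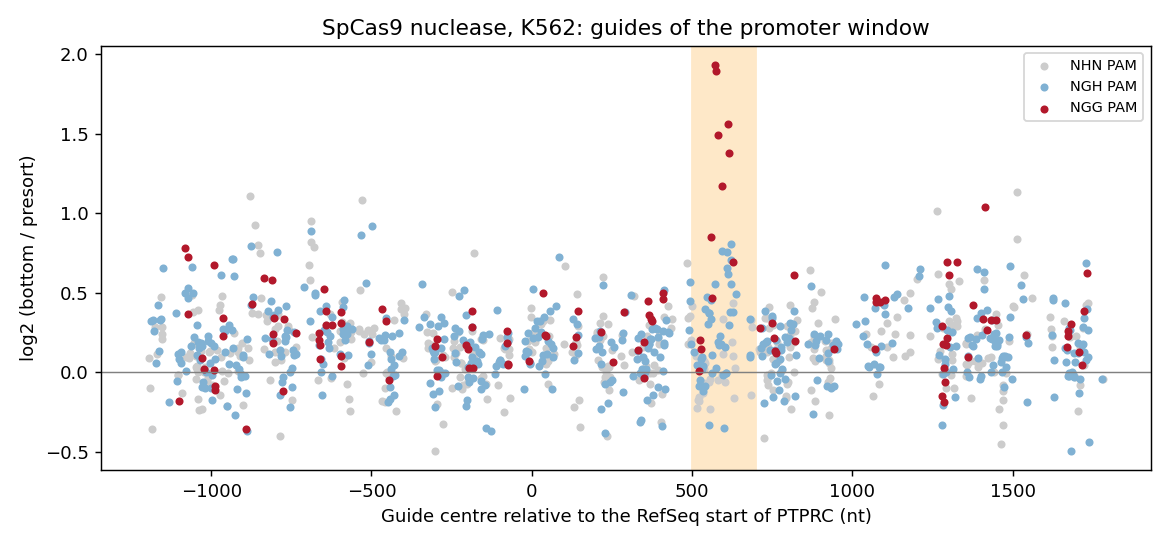
Log2 fold in the bottom bin of the SpCas9 nuclease for each guide of the promoter window (vertical axis) against its position relative to the RefSeq start of PTPRC in nt (horizontal axis), coloured by PAM class; the shaded band marks 500 to 700 nt. The 12 NGG guides in the band have a median of 1.01.

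The activation screen asked which PAMs the cleavage-dead activator forms of the 4 effectors could use to switch PTPRC on. NGG guides within 500 nt of the gene start were concentrated in CD45-high A375 cells with all effectors, at a median log2 fold of 1.35 (95% interval 0.83 to 1.97) with SpCas9, 0.77 (95% interval 0.50 to 1.35) with xCas9, 0.85 (95% interval 0.53 to 1.35) with Cas9-NG and 1.03 (95% interval 0.65 to 1.50) with xCas9-NG, over 36 guides each. NGH guides there were highest with xCas9-NG: their medians were 0.22, 0.20, 0.24 and 0.33 for SpCas9, xCas9, Cas9-NG and xCas9-NG. NHN guides there stood at 0.061, 0.12, 0.11 and 0.14. In the CD45-low bin the same NGG guides lay at -0.46, -0.28, -0.18 and -0.23. NGH guides stood there at -0.026 (-0.073 to 0.043), -0.044 (-0.089 to 0.025), -0.10 (-0.17 to -0.051) and -0.093 (-0.13 to -0.029), so the intervals of SpCas9 and xCas9 include 0.

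Of the NGG guides within 500 nt, 32 of 36, 28 of 36, 26 of 36 and 32 of 36 passed the 95th percentile of the non-targeting guides with SpCas9, xCas9, Cas9-NG and xCas9-NG. Of the NGH guides 44 of 187, 61 of 188, 56 of 188 and 89 of 188 passed, of the NHN guides 15 of 152, 15 of 152, 18 of 152 and 27 of 152, and 89 of 188 (47.3%, 40.0 to 54.7%) is the share for xCas9-NG with its interval. The 95th percentile differed between these libraries, at 0.47, 0.37, 0.45 and 0.35 in the same order, so counts compare non-targeting spread along with effectors. The NGH counts were 19, 51, 38 and 62 at the 99th percentile and 17, 11, 29 and 32 at a fixed 2-fold. Guides that also lay below 0 in the CD45-low bin numbered 24, 23, 22 and 26 for NGG, 29, 39, 45 and 61 for NGH, 9, 9, 8 and 13 for NHN and 4, 4, 6 and 5 for the non-targeting guides. NGG and NGH medians within 500 nt were higher than those of all 10000 matched random lists with each effector. With the abundance-dependent background the NGH medians were 0.20, 0.14, 0.19 and 0.22 and the NHN medians 0.056, 0.012, 0.041 and 0.028. Taken over the whole library, NGG medians were 0.22, 0.11, 0.091 and 0.23, NGH medians 0.076, 0.10, 0.10 and 0.17 and NHN medians 0.060, 0.081, 0.064 and 0.12.

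Against SpCas9, paired over guides within 500 nt, all 3 activation variants were lower at NGG and xCas9-NG was the furthest above SpCas9 at NGH. Over all guides the direction at NGG turned without centring, to 0.25, 0.38 and 0.64 for xCas9, Cas9-NG and xCas9-NG, and the order at NGH turned with the top over the bottom bin, at 0.079 for Cas9-NG and 0.069 for xCas9-NG. Within 500 nt the NGH medians of the top over the bottom bin were 0.29 for Cas9-NG and 0.33 for xCas9-NG, so the order did not turn there. At NGG the median paired difference was -0.36 (-0.63 to -0.17) for xCas9, -0.35 (-0.64 to -0.14) for Cas9-NG and -0.21 (-0.34 to -0.017) for xCas9-NG. At NGH it was 0.056 (0.0064 to 0.11) for xCas9, 0.13 (0.082 to 0.21) for Cas9-NG and 0.26 (0.20 to 0.31, higher in 138 of 187 guides) for xCas9-NG. For NHN guides the difference was 0.071 (-0.0039 to 0.12) for xCas9, 0.063 (-0.00070 to 0.13) for Cas9-NG and 0.14 (0.045 to 0.21) for xCas9-NG, so the NGH difference of xCas9 is no larger than its NHN difference. Split by PAM, the difference of xCas9-NG was 0.32 (0.17 to 0.40) at NGA, 0.24 (0.17 to 0.35) at NGT and 0.18 (0.049 to 0.31) at NGC. Non-targeting guides of xCas9-NG differed from those of SpCas9 by 0.052 (0.017 to 0.093), a shift seen without any target. With the abundance-dependent background the NGH difference of xCas9 turned to -0.0040 and that of xCas9-NG was 0.18.

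Over presort, xCas9-NG lay below Cas9-NG as a nuclease and above it as an activator, at NGG as well as at NGH. Paired over NGH guides in the region of effect, xCas9-NG lay -0.070 (-0.10 to -0.041) from Cas9-NG as a nuclease and 0.085 (0.038 to 0.10) from it as an activator. Over NGG guides it lay -0.069 (-0.10 to -0.010) and 0.11 (0.015 to 0.28) from Cas9-NG, and over NHN guides both intervals include 0. In the activation screen the unpaired medians of xCas9-NG also lay above those of Cas9-NG at coding guides, outside the promoter window. They were 0.11 against -0.021 (NGG), 0.092 against 0.054 (NGH) and 0.11 against 0.061 (NHN). The activation difference is therefore not confined to guides near the gene start. Cas9-NG exceeded xCas9 at NGH in both screens, by 0.11 (0.064 to 0.16) and 0.10 (0.035 to 0.15). These pairings between variants were not run with the abundance-dependent background. Under it, the NGH medians of Cas9-NG and xCas9-NG lay closer together for activation and further apart for the nuclease. With the sought bin over the other, over all guides, the NGH difference from SpCas9 was larger for Cas9-NG than for xCas9-NG in both screens, at 0.15 and 0.059 (nuclease) and 0.079 and 0.069 (activation), though not by the activation medians within 500 nt given above. The difference between screens was not tested, and cell line, effector type and guide region all differ between them.

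Active guides for PTPRC activation lay on both sides of the gene start. In 100-nt bins of NGG and NGH guides together, the medians from -400 to -300 nt (14 guides) were 0.27, 0.25, 0.67 and 0.89 with SpCas9, xCas9, Cas9-NG and xCas9-NG, and the intervals of SpCas9 (-0.22 to 1.12) and Cas9-NG (-0.14 to 1.15) include 0. The median of xCas9-NG was 0.066 from 0 to 100 nt (24 guides), 0.70 from 300 to 400 nt (38 guides) and 0.069 from 600 to 700 nt (19 guides). The 38 guides from 300 to 400 nt had medians of 0.48, 0.56, 0.54 and 0.70 with SpCas9, xCas9, Cas9-NG and xCas9-NG, and the 24 guides just past the start, from 0 to 100 nt, had 0.12, 0.0085, 0.036 and 0.066. Promoter NGG guides beyond 500 nt had medians of 0.21, 0.11, 0.068 and 0.20, and coding NGG guides -0.037, 0.039, -0.021 and 0.11. The highest 100-nt bin lay from 100 to 200 nt (10 guides) with SpCas9, at 0.71 (0.30 to 1.75), and with Cas9-NG, at 0.76 (0.14 to 1.89). It lay from 300 to 400 nt with xCas9 and from -400 to -300 nt with xCas9-NG. Bins hold 7 to 38 guides, so single bins under 20 guides place no peak.

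**Figure D4:**
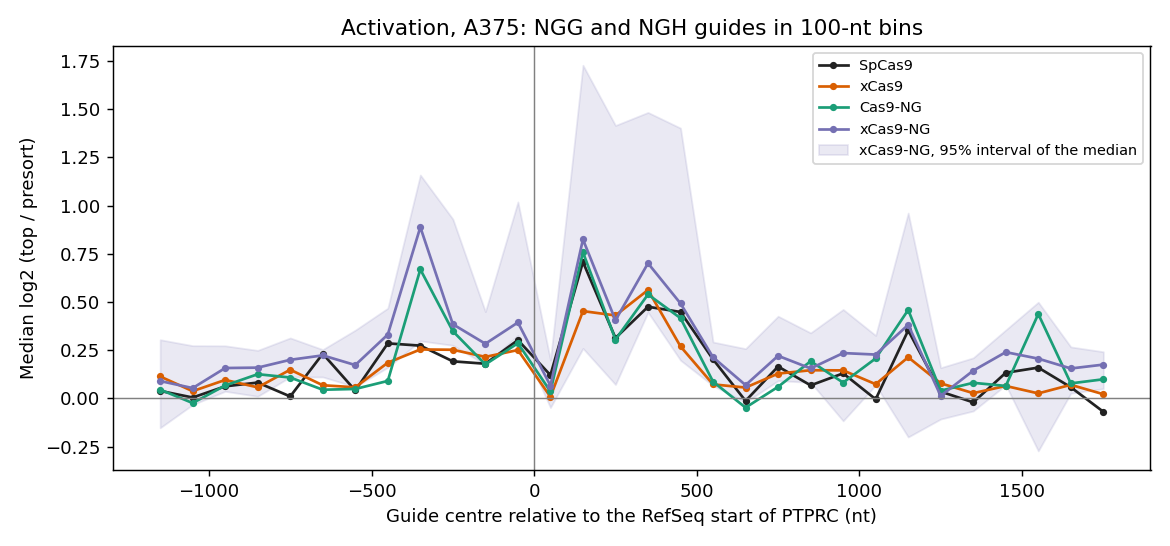
Median log2 fold in the top bin (vertical axis) of NGG and NGH guides in 100-nt bins along the promoter window (horizontal axis, nt from the RefSeq start of PTPRC), 1 line per effector, with the 95% order-statistic interval of xCas9-NG shaded. The lowest of the 4 medians from 300 to 400 nt is 0.48 and the highest from 0 to 100 nt is 0.12, both of SpCas9. The highest bin of SpCas9 and of Cas9-NG is 100 to 200 nt, over 10 guides.

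The strongest activation guide with SpCas9 was CCguide_00114 (TGG, minus strand, chromosome 1, 198638423 to 198638442), at a log2 fold of 2.77 (2.62 to 2.94; 2270 sorted against 380 presort reads), followed by CCguide_00122 (GGG, chromosome 1, 198638519 to 198638538) at 2.63 and CCguide_00059 (CGG, chromosome 1, 198639035 to 198639054) at 2.45. CCguide_00122 led with xCas9 at 2.77 (2.64 to 2.92; 3533 sorted against 464 presort reads), ahead of CCguide_00041 (TGG, chromosome 1, 198638956 to 198638975) at 2.44 and CCguide_00001 (GGG, chromosome 1, 198638629 to 198638648) at 2.38. CCguide_00016 (TGG, chromosome 1, 198639055 to 198639074) led with Cas9-NG at 2.62 and with xCas9-NG at 2.57 (2.45 to 2.71; 4560 sorted against 554 presort reads). CCguide_00005 (AGG, chromosome 1, 198639067 to 198639086) ranked 2 with Cas9-NG at 2.19, and CCguide_00059 ranked 2 with xCas9-NG at 2.42. One NGH guide stood among the first 3 of both NG variants: CCguide_00151 (TGT, plus strand, chromosome 1, 198639087 to 198639106) had 1.69, 1.37, 2.19 and 2.26 with SpCas9, xCas9, Cas9-NG and xCas9-NG, and was also the highest NGH guide of SpCas9. The highest NGH guide of xCas9 was CCguide_00505 (GGA, chromosome 1, 198638402 to 198638421) at 1.80, with an NGG PAM 1 base closer to its spacer. CCguide_00687 (GAG, chromosome 1, 198639115 to 198639134) was the highest NHN guide of Cas9-NG at 1.51 and of xCas9-NG at 1.54, and CCguide_01010 (ATT, chromosome 1, 198639259 to 198639278) that of SpCas9 at 1.24. The highest NHN guide of xCas9, CCguide_04939 (AAA, chromosome 1, 198709704 to 198709723), lies in coding segment 10 and rests on 112 presort reads, at 1.52.

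Guide folds correlated between the 4 effectors, over targeting and also over non-targeting guides. Across targeting guides, which are not independent replicates, Pearson correlations of the 6 pairs of effectors were 0.69 to 0.78 in the nuclease screen and 0.62 to 0.78 in the activation screen, and Spearman correlations 0.64 to 0.71 and 0.50 to 0.65. Within NGG guides of the region of effect, Pearson correlations were 0.75 to 0.88 and 0.76 to 0.96, the highest being Cas9-NG with xCas9-NG in both screens. Non-targeting guides, with no target, also correlated between effectors, at Pearson 0.44 to 0.61 and 0.31 to 0.60. Their Spearman correlations were 0.44 to 0.57 and 0.37 to 0.63, so part of the rank agreement was seen without a target. In activation most of it was. The gap between targeting and non-targeting guides was widest for SpCas9 with Cas9-NG, at 0.50 against 0.37. It was narrowest for xCas9 with xCas9-NG, at 0.65 against 0.63. Top and bottom folds of one effector share their presort library. With counting error only, this gives simulated correlations of 0.61 to 0.64 (nuclease) and 0.49 to 0.55 (activation) over NGG guides in the region of effect. Over non-targeting guides the observed correlations were 0.35 to 0.45 and 0.077 to 0.28. The simulation gave 0.62 to 0.65 and 0.48 to 0.54 for them, so it overstates the correlation expected without a target. For the NGG guides the observed correlations were below 0, at -0.60 to -0.36 and -0.86 to -0.65. Their covariances were -0.12 to -0.038 and -0.33 to -0.29 against simulated 0.0077 to 0.014 and 0.0038 to 0.0089.

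Effectors also shifted as a whole between sort bins. The share of nuclease pool reads held by xCas9 was 23.0% before sorting, 27.5% in the top bin and 16.5% in the bottom bin, while Cas9-NG held 23.8%, 19.5% and 28.2%. Among non-targeting reads alone xCas9 held 22.6%, 26.5% and 16.5%. In the activation pool xCas9-NG held 26.3% before sorting and 32.3% in the top bin, and SpCas9 15.4% and 11.3%. Before centring, the non-targeting medians were -0.0084, -0.61, 0.067 and -0.17 in the nuclease bottom bin and -0.57, -0.22, -0.10 and 0.094 in the activation top bin for SpCas9, xCas9, Cas9-NG and xCas9-NG, so folds are reported relative to them. Without that centring, over all guides, every PAM class median of the xCas9 nuclease and of SpCas9 and xCas9 activation lay below 0.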

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

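The tests on the promoter stretch and on NHN guides, and the abundance test on NGH guides, were chosen after the values were seen; the test on the first PAM base was written before its result. With 1 library per group, a result was taken up here where all 4 effectors moved one way in K562 and all 4 the opposite way in A375, which held for 5 of 18 combinations of PAM class, region and bin; the differences were not tested, and nuclease and activator differ together with the cell line. NGG guides of the whole promoter window had medians of -0.14 to -0.038 in the nuclease top bin and 0.15 to 0.34 in the activation top bin (means differing by -0.34, nuclease minus activation), and 0.25 to 0.28 against -0.081 to -0.0085 in the bottom bin (difference 0.31). Within 500 nt of the gene start, NGG medians were -0.17 to -0.030 against 0.77 to 1.35 in the top bin (difference -1.13) and 0.18 to 0.22 against -0.46 to -0.18 in the bottom bin (difference 0.49). NGH guides there had 0.13 to 0.18 against -0.10 to -0.026 in the bottom bin (difference 0.22). Promoter NHN guides of the nuclease bottom bin stood at 0.13, 0.14, 0.14 and 0.14, so the NGH level lies near that of targeting guides in general. The NGG level within 500 nt, at 0.18 to 0.22, lies only somewhat above it. The 500-nt window is part of the promoter window, so these combinations overlap.

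Promoter-window guides 500 to 700 nt past the gene start held the strongest nuclease guide of the 3 variants. Low presort abundance does not account for their enrichment, since the NGG median with SpCas9 was 0.98 after the abundance background was subtracted. NGG guides exceeded NHN guides of the same stretch by at least 0.56 with every effector, and the CD45-high medians of these NGG guides were -0.73, -0.40, -0.40 and -0.29. The stretch was picked for its high NGG guides, so their excess over NHN guides was largely set in advance and decides nothing about the cause. A candidate explanation is that they cut a coding or splice sequence, since the coding segments named in the library start at number 2; exon positions were not used here, so this stays a hypothesis.

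Coding NGA and NGT guides were enriched with SpCas9 itself, which prefers NGG, and carried the NGH result: their medians were 0.26 and 0.32, while coding NGC guides, at 0.12 with 20% past the threshold, were close to coding NHN guides, at 0.10 with 22.8%. In the CD45-high bin the NGT guides lay below 0, at -0.076 (-0.14 to -0.018), while the NGA guides stood at -0.0066 (-0.055 to 0.064). The tests here ran on all NGH guides together. Presort abundance does not account for all of it: the median after the abundance background was 0.11 (interval 0.078 to 0.14). An NGG PAM 1 base closer to the spacer, present where the PAM starts with G, does not account for it either: the 187 guides with another first PAM base had a corrected median of 0.11 (interval 0.071 to 0.14), against 0.10 (0.049 to 0.21) for guides with G. Before the correction, guides with G differed from the others by 0.0061 (-0.14 to 0.085). Activity of SpCas9 at relaxed PAMs may remain as an explanation and was not tested apart from these values.

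NHN guides lay slightly above the non-targeting guides in the nuclease bottom bin. Their lower presort abundance does not account for all of it: the median residual over the line fitted to non-targeting guides was at least 0.072 with every effector. Cutting of the coding sequence does not account for it, because coding NHN guides were not higher than promoter NHN guides (largest difference -0.0014, with intervals reaching at most 0.025). The residuals in the nuclease top bin were -0.0086 to 0.031 and in the activation top bin -0.032 to 0.038. A test on activation guides against the coding sequence was named first and was replaced before it was run, after their medians had been seen; their residuals in the top bin were -0.016, -0.025, -0.030 and 0.034. What sets targeting NHN guides apart from the non-targeting guides stays open, and a response to cutting at any site in the locus was not tested.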

How the results depend on the processing

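The background by presort abundance, the settings of medians within the region of effect and the region-limited differences were chosen after seeing the data. Values are given in the order SpCas9, xCas9, Cas9-NG and xCas9-NG, or for differences the 3 variants, and causes were not tested except where the construction shows them. All 24 medians over all guides stayed within their intervals with a pseudocount of 0.1, with no presort minimum and with guides past the minimum for all effectors, and all 24 region-limited medians with a pseudocount of 10 and a minimum of 100 reads. With a pseudocount of 10, 1 of the 24 all-guide medians left its interval (nuclease Cas9-NG NHN, 0.13), and with 100 presort reads 1 did (nuclease xCas9 NHN, 0.11). Without centring, the whole-effector shift enters each median: nuclease NGG 0.35, -0.27, 0.42 and 0.21, NGH 0.17, -0.41, 0.30 and 0.052, NHN 0.11, -0.48, 0.20 and -0.030, activation NGG -0.35, -0.11, -0.0048 and 0.32, NGH -0.49, -0.11, 0.0082 and 0.27, NHN -0.51, -0.13, -0.032 and 0.22, which turns all xCas9 nuclease medians, the NHN median of the xCas9-NG nuclease, all SpCas9 and xCas9 activation medians and the NGG and NHN medians of Cas9-NG activation below 0. Centring on all guides, most of which target PTPRC, gave nuclease NGG 0.22, 0.20, 0.19 and 0.21, NGH 0.040, 0.050, 0.070 and 0.057, NHN -0.017, -0.021, -0.027 and -0.025, activation NGG 0.15, 0.032, 0.020 and 0.092, NGH 0.013, 0.026, 0.033 and 0.038, NHN -0.0033, 0.0023, -0.0067 and -0.015, with NHN below 0 except for xCas9 activation. Guides of the region of effect alone gave nuclease NGG 1.13, 0.60, 0.67 and 0.57, NGH 0.24, 0.26, 0.31 and 0.27, NHN 0.10, 0.12, 0.14 and 0.13, activation NGG 1.35, 0.77, 0.85 and 1.03, NGH 0.22, 0.20, 0.24 and 0.33, NHN 0.061, 0.12, 0.11 and 0.14. The abundance background gave region-limited medians of NGG 0.96, 0.45, 0.54 and 0.48, NGH 0.11, 0.12, 0.19 and 0.13, NHN 0.0031, 0.0095, 0.018 and 0.012 for the nuclease and NGG 1.36, 0.67, 0.81 and 0.87, NGH 0.20, 0.14, 0.19 and 0.22, NHN 0.056, 0.012, 0.041 and 0.028 for activation, and the sought bin over the other bin NGG 1.56, 0.63, 0.93 and 0.72, NGH 0.20, 0.19, 0.37 and 0.23, NHN 0.070, 0.045, 0.11 and 0.051 and NGG 1.78, 0.90, 0.99 and 1.21, NGH 0.20, 0.20, 0.29 and 0.33, NHN 0.052, 0.060, 0.089 and 0.052. All-guide differences from SpCas9 were NGG -0.13, -0.083 and -0.060, NGH 0.026, 0.075 and 0.060, NHN 0.012, 0.015 and 0.024 (nuclease) and NGG -0.10, -0.10 and -0.021, NGH 0.046, 0.067 and 0.14, NHN 0.043, 0.017 and 0.087 (activation), and stayed within their intervals with 100 presort reads. They became NGG -0.74, -0.0083 and -0.22, NGH -0.58, 0.15 and -0.10, NHN -0.59, 0.090 and -0.13 and NGG 0.25, 0.38 and 0.64, NGH 0.40, 0.54 and 0.80, NHN 0.39, 0.49 and 0.75 without centring, NGG -0.21, -0.061 and -0.14, NGH -0.025, 0.15 and 0.059, NHN -0.040, 0.037 and -0.022 and NGG -0.18, -0.18 and -0.13, NGH 0.0034, 0.079 and 0.069, NHN 0.0057, 0.019 and 0.0044 with the sought bin over the other, NGG -0.52, -0.31 and -0.42, NGH 0.023, 0.12 and 0.063, NHN 0.0082, 0.032 and 0.024 and NGG -0.36, -0.35 and -0.21, NGH 0.056, 0.13 and 0.26, NHN 0.071, 0.063 and 0.14 in the region of effect, and for activation with a pseudocount of 10 NGH 0.022, 0.024 and 0.093, NHN 0.020, -0.0085 and 0.053. Directions at NGG stayed below 0 in all of these except activation without centring; the NGH and NHN differences of the xCas9 nuclease and the NHN difference of the xCas9-NG nuclease turned below 0 both without centring and with the sought bin over the other, the NGH difference of the xCas9-NG nuclease without centring, and the NHN difference of Cas9-NG activation with a pseudocount of 10. Region-limited differences with the abundance background left their intervals for activation xCas9 at NGH, which turned to -0.0040, and xCas9-NG at NGH (0.18); that of activation xCas9 at NHN also turned, to -0.0035, within its interval.

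Counts of enriched guides moved with the threshold. In the region of effect they were NGG 48, 43, 44 and 45, NGH 101, 85, 121 and 110, NHN 102, 80, 103 and 115 for the nuclease and NGG 32, 28, 26 and 32, NGH 44, 61, 56 and 89, NHN 15, 15, 18 and 27 for activation. They became NGG 45, 37, 41 and 39, NGH 46, 55, 93 and 76, NHN 37, 43, 61 and 59 and NGG 23, 27, 20 and 28, NGH 19, 51, 38 and 62, NHN 4, 8, 5 and 18 at the 99th percentile, NGG 29, 6, 13 and 6, NGH 0, 3, 21 and 11, NHN 4, 1, 5 and 3 and NGG 22, 15, 17 and 18, NGH 17, 11, 29 and 32, NHN 2, 0, 4 and 5 at a fixed 2-fold, and NGG 45, 34, 36 and 36, NGH 57, 35, 85 and 64, NHN 20, 9, 26 and 18 and NGG 24, 23, 22 and 26, NGH 29, 39, 45 and 61, NHN 9, 9, 8 and 13 where a fold below 0 in the opposite bin was also required. Over all guides they were NGG 104, 90, 104 and 105, NGH 239, 219, 313 and 304, NHN 213, 176, 217 and 244 and NGG 54, 38, 36 and 60, NGH 100, 126, 111 and 198, NHN 91, 90, 73 and 162, with NGG 69, 60, 77 and 77, NGH 102, 131, 208 and 193, NHN 73, 101, 123 and 135 and NGG 30, 34, 20 and 37, NGH 30, 86, 47 and 117, NHN 14, 54, 18 and 81 at the 99th percentile, NGG 36, 9, 16 and 9, NGH 0, 4, 29 and 21, NHN 8, 5, 8 and 5 and NGG 27, 17, 17 and 18, NGH 24, 11, 32 and 32, NHN 8, 4, 9 and 8 at 2-fold, and NGG 83, 55, 67 and 66, NGH 86, 68, 157 and 139, NHN 32, 13, 35 and 27 and NGG 32, 29, 27 and 34, NGH 49, 60, 62 and 92, NHN 29, 29, 29 and 31 with the opposite bin required. All 48 counts stayed within 1.5 times with a pseudocount of 10 and with 100 presort reads. For the 38 named guide values the sought bin over the other is above 0 by the naming rule, so that alternative does not test them; with a pseudocount of 10, 3 of the 38 left their intervals. Correlations between effectors within NGH guides were 0.65 to 0.77 and 0.64 to 0.80, and within NHN guides 0.63 to 0.72 and 0.46 to 0.65 (nuclease and activation). In 50-nt bins the start of the highest activation bin moved for xCas9 from 300 to 250 nt and for xCas9-NG from -400 to 100 nt. Each of these 50-nt bins held 8 guides. The alternative without guides holding a T stretch or an extreme GC content was not run, because spacer sequences were not used here, and no library could be left out with 1 per group. No pairing of replicates was possible because each group has 1 library and the labels give no replicate numbers. The folds do pair the sorted and presort libraries of the same effector. Depth limits single guides more than classes. The lowest presort median was 263 reads per guide, with SpCas9 activation. Over non-targeting guides, counting error alone gives a standard deviation of up to 0.12 on the log2 scale. NHN guides were less abundant before sorting than non-targeting guides, so counting error is larger for them.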

Other observations

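The comparison of strands and the abundance line for the xCas9 shift were chosen after seeing the data. Guides on the plus strand had higher activation medians than guides on the minus strand within 500 nt of the gene start. For NGG the medians were 1.75 (1.10 to 2.19, 17 guides) on the plus strand and 0.94 (0.60 to 1.87, 19 guides) on the minus strand with SpCas9, and 1.01 and 0.58 with xCas9, 1.13 and 0.81 with Cas9-NG, 1.48 and 0.84 with xCas9-NG. The intervals overlap for each effector, and the difference was not tested. For NGH guides the plus-strand medians were 0.30, 0.21, 0.30 and 0.36 and the minus-strand medians 0.15, 0.20, 0.15 and 0.29.

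In the nuclease screen, NHN guides of coding segment 10 had a median of 0.29 (0.14 to 0.41) with SpCas9 over 48 guides, against 0.021 (-0.029 to 0.056) over 44 guides in segment 12. The same guides of segment 10 stood at 0.11 in the CD45-high bin, so both bins lay above the non-targeting guides. The opposite pattern, high in one bin and low in the other, was seen for NGG guides of segment 13 with SpCas9, at 1.19 and -0.78. Of the 250 non-targeting guides of the xCas9 nuclease, 100% had a lower share of pool reads in the bottom bin than before sorting, and 6% had a lower share in the top bin. The median shift in the bottom bin was -0.61, and the line of fold on presort abundance through the non-targeting guides of the other 3 effectors gave -0.019 at the abundance of xCas9, so neither a few guides nor presort abundance accounts for it. With 1 culture per effector, effector and culture are the same division of the libraries, and this shift was not taken further.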
